A study of Homo sapiens with 16 samples.

How the data were processed

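Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 histone marks in Toledo cells, an established diffuse large B-cell lymphoma line. Per the labels, the cells were kept for 6 days with 5 uM TP-064, an inhibitor of the arginine methyltransferase CARM1, or with the solvent DMSO. The antibodies recognised H3K27ac, H3K4me1 and H3K4me3. Each mark and treatment had 2 libraries, giving 12 ChIP libraries, and 4 input libraries complete the 16 samples. Input files were not used here.

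Per the submitters' processing notes, Bowtie 1.1.2, MACS 1.4.2 and the build hg38 were used. The role of the inputs, the peak threshold and the read filters are not given in the sources used here. The authors deposited 1 peak list per ChIP library, so peaks were called in each library separately. Each deposited list holds 3 columns (chromosome, start and end) and no score, height or p-value. No list held peaks outside chromosomes 1 to 22 and X, and no peaks within a list overlapped or touched.

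Read depth is unknown, because the lists carry no reads. A peak absent from a list may therefore be a site below the caller's threshold, and the number of peaks can follow depth and enrichment as well as the mark. Peaks were compared by presence and absence, and their width in bp served where a score had been planned for ranking. Before the data were examined, stricter score thresholds and the best peaks by score had been chosen as alternatives. The former could not be run, and the latter was run on the widest peaks instead. Restricting the lists to chromosomes 1 to 22 and X removed nothing.

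Peaks of the 4 libraries of a mark were merged into regions where they overlapped by at least 1 bp or touched. A region was called lost when both DMSO libraries and neither CARM1 inhibitor library had a peak in it, and gained in the opposite case. The counts were set beside those from the other 2 ways of splitting the 4 libraries into pairs. Genes were the 19970 protein-coding genes of the GRCh38.p14 RefSeq table on these chromosomes. That table was used without strand, exons or transcripts, so the planned windows around the 5' end were replaced by windows around both ends of a gene. The windows reached 2 kb for H3K27ac and H3K4me3 and 10 kb for H3K4me1. A neighbouring gene's peak can fall in such a window: 58.7% of the genes that lost H3K27ac had DMSO peaks in both libraries that touched no other gene's window, against 40.5% for H3K4me1 and 76.1% for H3K4me3. Positions of peaks (within 2 kb of a gene end, elsewhere in a gene body, or between genes) used the same table.

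The 16 gene lists were fixed at that point as well: antigen presentation by MHC class II and class I, B-cell identity, the germinal centre programme, germinal centre exit, NF-kB targets, interferon response, cell cycle, MYC and ribosome biogenesis, p53 targets, immediate early genes, acetyltransferases and coactivators, ribosomal proteins as a control, and markers of T and NK, myeloid, and epithelial and stromal cells. For loss, genes with a peak in both DMSO libraries were the background, and for gain those with a peak in neither. One-sided Fisher's exact tests were run where a list had at least 3 background genes. Benjamini-Hochberg adjustment covered all lists and marks, with a threshold of 0.05.

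The genes named were also fixed by rule. They are the 10 lost and 10 gained genes per mark with the highest within-list width percentile (the lower of the 2 libraries), lost or gained list members up to 10 per list, and 10 genes named in every mark whatever their state. The rule adds the 3 lost and 3 gained regions of highest rank and the 5 widest H3K27ac and H3K4me3 regions present in all 4 libraries. A representative part of these is described. Some list members are counted but not reported by name here.

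Peak numbers and shares were compared by a two-sided exact permutation test over the 6 assignments of 4 libraries, for which 0.333 is the smallest p possible. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels put all DMSO libraries on lane 3 and all CARM1 inhibitor libraries on lane 4, so lane and treatment cannot be told apart. Overlap between lists was measured as the Jaccard index of covered base pairs.

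The code was tested on simulated data. With 200 lost and 100 gained regions planted among 10288 H3K27ac, 25624 H3K4me1 or 12970 H3K4me3 regions, all were recovered. Unchanged lists gave p under 0.05 in 1.58%, 3.43% and 2.57% of tests on 2329, 4254 and 10800 background genes. A planted list of 30 genes, 60% lost against 20%, had an unadjusted p under 0.05 by Fisher's exact test in 100, 100 and 99 of 100 runs. Loss was drawn gene by gene at 20% for each mark, without shared peaks or drop-out by width, and no simulated region lost a peak at random. The simulations therefore check the code and give no error rate or power for the adjusted tests on these data.

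Alternatives varied the overlap, the merging gap, the gene window, the libraries used and the length of the lists, and random lists matched on peak width replaced the Fisher test. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

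No list held a peak between positions 28400396 and 33507946 of chromosome 6, which contains 173 protein-coding genes including the MHC genes. In all, 11 of the 18 MHC class II list members and 10 of the 16 class I members lie there. They counted as genes without a peak in the backgrounds for gain, and an alternative chosen after seeing the data left out the 1065 genes in such stretches. Other stretches without a peak in any list held 36 protein-coding genes on chromosome 15 (27865933 to 33188084) and 33 on chromosome 17 (35765509 to 37608704).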

Results

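Acetylation of histone H3 at lysine 27 (H3K27ac) marks active promoters and enhancers, H3K4me3 marks promoters and H3K4me1 marks mainly enhancers. The 3 marks were mapped in Toledo lymphoma cells after 6 days with 5 uM TP-064, which inhibits CARM1, or with DMSO. The study's title places the work on the question of whether CARM1 inhibition lowers histone acetyltransferase activity in lymphomas with mutated CREBBP or EP300, the genes of the acetyltransferases that place H3K27ac. Each mark and treatment had 2 libraries. The H3K27ac lists held 7885 and 4016 peaks with DMSO and 4771 and 4595 with the inhibitor. The H3K4me1 lists held 25058 and 9673 against 4094 and 4242, and the H3K4me3 lists 12476 and 11481 against 10317 and 10048. Read depth is unknown.

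The first comparison asked how many sites carried each mark. H3K4me1 peaks numbered 17366 ± 10879 (SD, n = 2) with DMSO and 4168 ± 105 with the inhibitor, a log2 ratio of -2.06, with an exact permutation p of 0.333. They covered 60.4 and 22.1 Mb with DMSO and 9.11 and 8.30 Mb with the inhibitor. H3K4me3 peaks numbered 11979 ± 704 against 10183 ± 190, a log2 ratio of -0.23 (exact permutation p = 0.333), and covered 26.8 ± 2.4 Mb against 19.9 ± 1.4 Mb. For H3K27ac the means were 5951 ± 2736 and 4683 ± 124, a log2 ratio of -0.35, which lay within the spread between the DMSO libraries (exact permutation p = 1). The design allows no p below 0.333. The DMSO libraries themselves differed 1.96-fold for H3K27ac, 2.59-fold for H3K4me1 and 1.09-fold for H3K4me3, and without DMSO replicate 1 the H3K27ac log2 ratio turned to 0.22 and the H3K4me1 ratio shrank to -1.21. Without DMSO replicate 2 the H3K27ac ratio was -0.75.

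**Figure D1:**
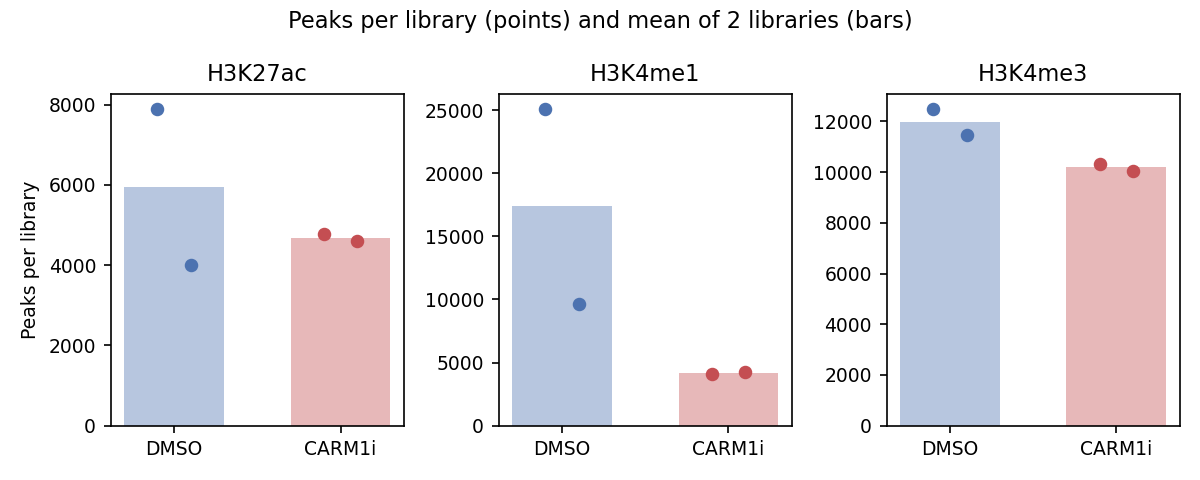
Peaks per library for H3K27ac, H3K4me1 and H3K4me3 (vertical axes, number of peaks, each with its own scale), with points for the 2 libraries of each treatment and bars for their mean. For H3K4me1 and H3K4me3 both CARM1 inhibitor libraries lie below both DMSO libraries, while for H3K27ac they lie between the DMSO values of 7885 and 4016.

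H3K27ac was lost at E2F2, a transcription factor of the cell cycle, where DMSO peaks of 6968 and 2565 bp at the gene end had no counterpart in either inhibitor library. It was also lost at SLAMF6, a lymphocyte surface receptor (4783 and 4499 bp), and at GAPDH, a glycolytic enzyme (3019 and 2385 bp). FCRL2, an Fc receptor-like protein of B cells, counted as lost too, but its widest DMSO peaks (7600 and 3361 bp) did not overlap each other. The lost region of highest rank by width percentile lay at AMN and CDC42BPB (chromosome 14, 102930570 to 102938646), followed by a region beside TRAF3, an inhibitor of NF-kB signalling (chromosome 14, 102912020 to 102918472). Genes that gained H3K27ac included ZBTB7B, a transcription factor (3268 and 2867 bp with the inhibitor), PER2, a circadian clock gene (2914 and 2856 bp), LAG3, an inhibitory immune receptor (2722 and 3223 bp), and HBEGF, a growth factor (2217 and 2189 bp). The gained regions of highest rank lay near RALGPS2 (chromosome 1, 178931033 to 178936577), PPM1H (chromosome 12, 62916287 to 62923727) and AFG2A (chromosome 4, 123257063 to 123261690). The states at gene ends depended on the window for SLAMF6, ZBTB7B and PER2, which were no longer lost or gained with windows halved, and for SLAMF6, FCRL2, PER2 and LAG3 with windows 2.5 times as wide. GAPDH was no longer lost when peaks at the ends of 1 gene only were counted, and E2F2 and HBEGF kept their state under these settings. Strand was not used, so the end that lost or gained a peak need not be the promoter. The widest inhibitor peaks lay outside PER2, below its lower coordinate, and across the upper coordinate of LAG3. The widest DMSO peaks of SLAMF6 lay near its lower coordinate.

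Of 10288 H3K27ac regions, 812 were lost, 390 were gained and 1878 had a peak in all 4 libraries. The 1202 changed regions compare with 489 and 304 in the other 2 splits of the libraries. At the level of genes, 651 of 2329 genes with H3K27ac in both DMSO libraries lost it (28.0%) and 62 genes gained it. Of the 651 genes, 626 (96.2%) had H3K4me3 in all 4 libraries, as did 2214 of the 2329 (95.1%). Among the regions in all 4 libraries, those with the largest mean covered length lay in or near IGLL5, RUBCNL, SPAG16, MSI2 and MEF2D. The counts moved with single libraries: lost regions numbered 1303 without DMSO replicate 1, 3861 without DMSO replicate 2 and 1222 without inhibitor replicate 1, and gained regions 1069 without DMSO replicate 1, 1334 without inhibitor replicate 1 and 1112 without inhibitor replicate 2. Genes that lost H3K27ac numbered 2483 of 4842 (51.3%) without DMSO replicate 2 and 996 without inhibitor replicate 1, and genes that gained it 299 without DMSO replicate 1, 143 without inhibitor replicate 1 and 176 without inhibitor replicate 2. In lists restricted to the widest 4016 peaks, an alternative chosen after seeing the data, 463 regions were lost and 495 gained.

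The position of H3K27ac peaks was compared next. Peaks within 2 kb of a gene end made up 51.4% ± 0.2 (SD, n = 2) of the H3K27ac peaks with DMSO and 37.0% ± 2.9 with the inhibitor, a difference of -14.4 percentage points (exact permutation p = 0.333). The share in gene bodies was 26.1% ± 0.3 against 32.1% ± 1.3, and between genes 22.5% ± 0.5 against 30.8% ± 4.2. Lost H3K27ac regions lay at gene ends in 67.1% of cases and at DMSO H3K4me3 peaks in 76.8%, gained regions in 16.9% and 13.1%, and regions in all 4 libraries in 50.4% and 58.9%. An H3K4me1 peak of the DMSO libraries overlapped 66.4% of the lost regions, 73.6% of the gained regions and 85.8% of those in all 4 libraries. Among the 3319 regions with H3K27ac in both DMSO libraries, 28.3% of those at gene ends and 19.2% of the others were lost. Compared within deciles of DMSO peak width, that difference was -1.95 percentage points (95% interval -4.70 to 0.79), so the higher loss at gene ends was not seen among peaks of similar width. The interval treats regions as independent and leaves out the spread between libraries.

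**Figure D2:**
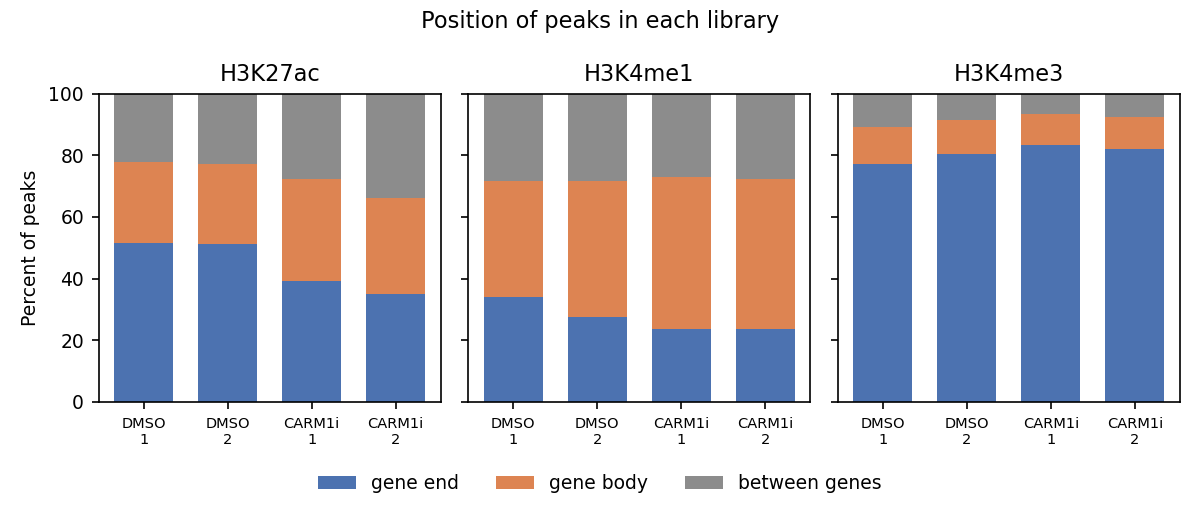
Share of peaks (vertical axis, percent) within 2 kb of a gene end, elsewhere in a gene body and between genes, for each of the 4 libraries of each mark (horizontal axis). For H3K27ac the gene-end share is 51.5% and 51.3% in the DMSO libraries and 39.1% and 35.0% in the CARM1 inhibitor libraries.

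H3K27ac peaks were then sorted by the methylation marks of the same treatment and replicate. With DMSO, 57.4% ± 1.0 (SD, n = 2) overlapped H3K4me3, 31.7% ± 4.8 H3K4me1 only and 10.8% ± 5.7 neither. With the inhibitor these shares were 38.2% ± 3.8, 21.5% ± 0.7 and 40.4% ± 4.5 (exact permutation p = 0.333 for each). The last 2 shares depend on the short H3K4me1 lists of the inhibitor libraries. Against 1 set of sites from all lists, an alternative chosen after seeing the data, the share at H3K4me1 only turned from a difference of -10.3 to 10.7 percentage points, and the share at neither shrank from a difference of 29.5 to 5.30. The latter rested on inhibitor replicate 2 (17.0%), since inhibitor replicate 1 had 8.87% and the DMSO libraries 6.42% and 8.86%. The difference at H3K4me3 was -16.0 percentage points with that set.

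Cell cycle genes lost H3K27ac more often than other genes. Of the 19 list members with H3K27ac in both DMSO libraries, 14 lost it (73.7%, against 27.6% of other genes; one-sided Fisher's exact test, p = 4.25e-05, adjusted p = 0.0017). They include MKI67, a proliferation marker (DMSO peaks of 1314 and 1055 bp), the kinases CDK4 (2564 and 1368 bp) and AURKA (2156 and 1936 bp), the replication helicase subunits MCM3, MCM4 and MCM5, the ribonucleotide reductase subunits RRM1 and RRM2, and the transcription factors E2F2 and E2F8. BIRC5, FOXM1, MYBL2 and TYMS, outside the rule for named genes and named after their values were seen, are the others. In a permutation test with random lists matched on DMSO peak width, chosen after seeing the data, the lists had 5.86 losses on average and p was 0.0001, the smallest that 10000 lists can give. The call ended when any part of the gene counted in place of its ends, also chosen after seeing the data (Fisher's exact test, adjusted p = 0.0517), and adjusted p ranged from 0.00137 to that value over the alternatives. Without DMSO replicate 2, 81.8% of the list members with H3K27ac in DMSO replicate 1 lost it, against 51.1% of other genes. In that setting the ribosomal protein genes, the control list, lost it nearly as often (78.8%). Genes are not replicates, and these tests describe the libraries at hand.

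**Figure D3:**
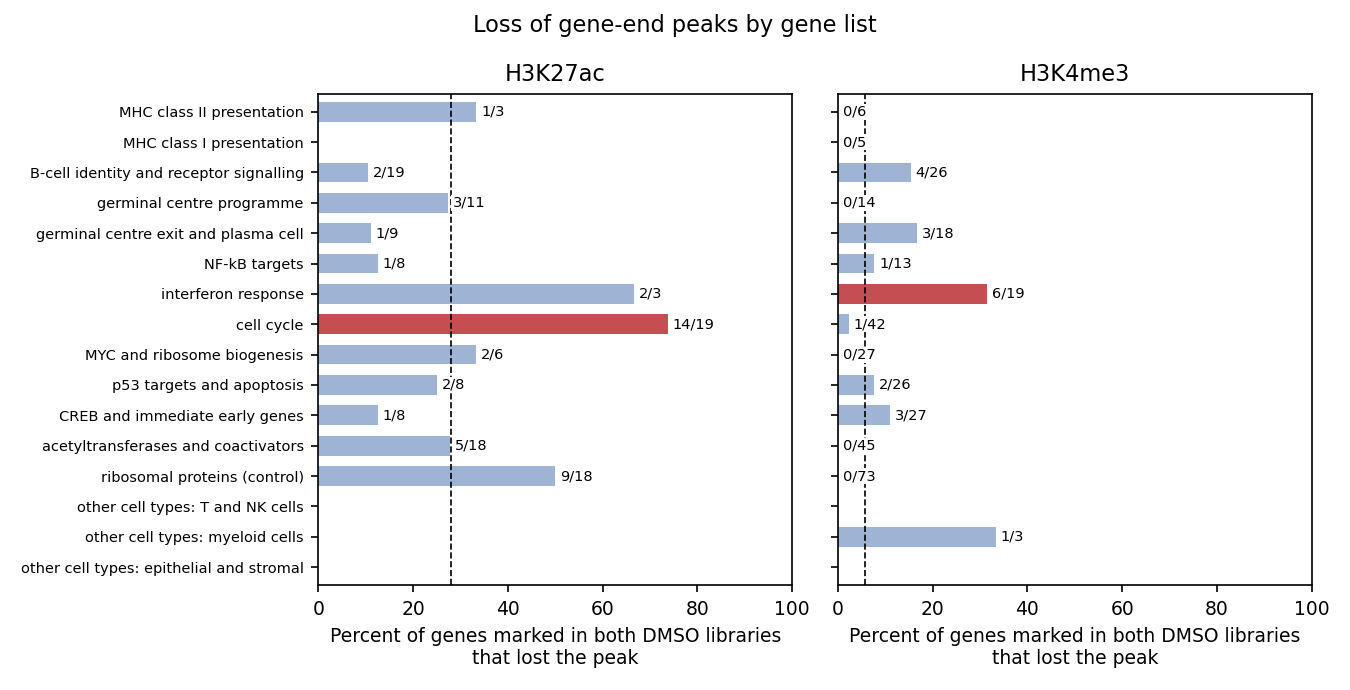
Percent of the genes marked in both DMSO libraries that lost the mark (horizontal axis) for each gene list (vertical axis), for H3K27ac and H3K4me3, with bars labelled by lost and background genes, red for an adjusted p below 0.05, dashed lines for all genes (28.0% and 5.67%), and no bar under 3 background genes. Cell cycle stands at 14 of 19 for H3K27ac and interferon response at 6 of 19 for H3K4me3.

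**Figure D4:**
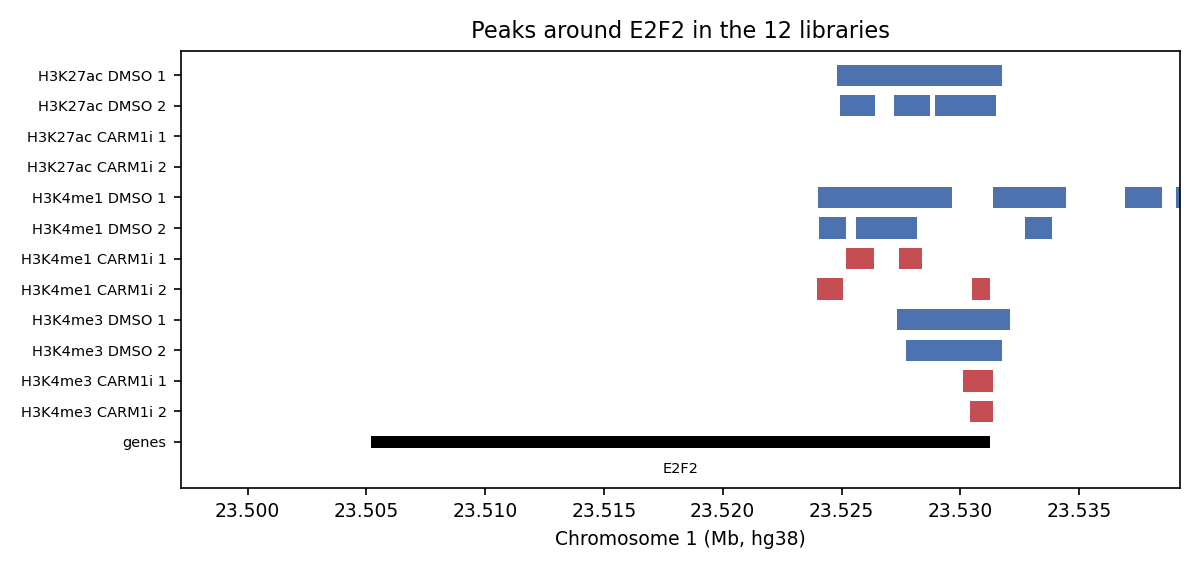
Peaks of the 12 libraries (bars, blue for DMSO and red for CARM1 inhibitor) around E2F2 on chromosome 1 (horizontal axis, Mb, hg38), with the gene in black. H3K27ac peaks are present in the DMSO libraries only, and the H3K4me3 peaks of 4756 and 4046 bp with DMSO are 1244 and 961 bp wide with the inhibitor.

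Other lists did not pass the test for H3K27ac loss. Ribosomal protein genes, the control list, lost it at 9 of 18 (RPL7A, RPL22 and RPS14 among them; unadjusted p = 0.0385, adjusted p = 0.513 by Fisher's exact test), and without DMSO replicate 2 that list passed (adjusted p = 0.00153). Without inhibitor replicate 1 its difference from other genes went from 22.2 to 12.9 percentage points. Of the acetyltransferase and coactivator genes 5 of 18 lost the peak, namely CREBBP, PRMT1, PRMT3, KMT2B and KDM1A. B-cell identity genes lost it at 2 of 19 (SPI1 among them), 10.5% against 28.1% of other genes, and the one-sided tests could not call such lower loss. Germinal centre genes lost the peak at 3 of 11 (BCL6, ELL3 and NEIL1) and germinal centre exit genes at 1 of 9 (XBP1). The counts were 1 of 8 for NF-kB targets (BCL3), 2 of 3 for interferon response (IRF1 and DTX3L), 2 of 6 for MYC and ribosome biogenesis (ENO1 and NOP56), 2 of 8 for p53 targets (BCL2L11 among them), 1 of 8 for immediate early genes (IER5) and 1 of 3 for MHC class II presentation (RFXANK). MHC class I presentation, T and NK, myeloid, and epithelial and stromal lists had fewer than 3 background genes.

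For gain, 0 of 42 list tests over the marks passed after adjustment by Fisher's exact test, and 0 had an unadjusted p under 0.05. The backgrounds of these tests include genes in long stretches without a peak in any list, such as most MHC genes. Without the 1065 genes in such stretches, an alternative chosen after seeing the data, 0 of 35 tests passed by Fisher's exact test and 0 had an unadjusted p under 0.05. ZMAT3, a p53 target, was the list member that gained H3K27ac.

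H3K4me3 was lost at ADM, which encodes the peptide hormone adrenomedullin, and at the neighbouring SBF2 (1 shared region, chromosome 11, 10302255 to 10308674). It was also lost at KLHL14 (5096 and 4312 bp with DMSO), at ZFP36L1, an RNA-binding protein that promotes mRNA decay (7294 and 3686 bp), at BMP7, a growth factor (3660 and 3524 bp), and at HMGB3 (3140 and 3037 bp). A region at SKOR1 (chromosome 15, 67831813 to 67836642) ranked among the first lost regions. Gains were few: YPEL4 was the gene that gained H3K4me3 at its ends (2118 and 2014 bp with the inhibitor), and the gained regions of highest rank lay in RABGAP1L, OR10J1 and SLC16A7. ZFP36L1 was no longer lost with windows 2.5 times as wide, HMGB3 with those or with windows halved, and ADM and SBF2 when peaks at the ends of 1 gene only were counted. Among the regions in all 4 libraries, those with the largest mean covered length lay at PAX5, the B-cell identity factor, where 15441 and 15026 bp were covered with DMSO and 12587 and 10841 bp with the inhibitor, and at IRF2BP2, IKZF2 and BCL11A, with 1 more at 170566 bp from PTPRC.

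Of 12970 H3K4me3 regions, 1237 were lost, 12 gained and 9477 present in all 4 libraries, against 43 and 6 changed regions in the other 2 splits and 1249 in the real split. At genes, 612 of 10800 lost the mark (5.67%), against 945 without DMSO replicate 2 and 989 without inhibitor replicate 1, and 1 gene gained it, against 4 without DMSO replicate 1 and 5 when inhibitor replicate 1 or replicate 2 was left out. Regions in all 4 libraries were narrower in both inhibitor libraries than in both DMSO libraries in 7762 cases (81.9%), with a median log2 ratio of covered length of -0.27. Lost regions had narrow DMSO peaks, at a median width percentile of 9.16 in the DMSO replicate 2 list, against 57.7 for regions kept in all 4 libraries. Lost regions numbered 2276 without DMSO replicate 2, and gained regions 23 without DMSO replicate 1, 386 without inhibitor replicate 1 and 91 without inhibitor replicate 2. In lists of equal length, an alternative chosen after seeing the data, 390 were lost and 188 gained. The gene-end share was 78.7% ± 2.3 with DMSO and 82.6% ± 0.7 (SD, n = 2) with the inhibitor (exact permutation p = 0.333), and the difference of 3.90 percentage points was 2.25 without DMSO replicate 1 and turned to -1.09 in lists of equal length.

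Interferon response genes lost H3K4me3 at 6 of 19 (31.6%, against 5.62% of other genes; one-sided Fisher's exact test, adjusted p = 0.00928). The 6 were IFIT2, MX1, IFI35, USP18, SP110 and PARP9, each with DMSO peaks between 1047 and 1981 bp wide. The call did not hold in a permutation test against random lists matched on peak width (adjusted p = 0.218) or in Fisher's exact test with the whole gene in place of its ends (adjusted p = 0.0892). In lists of equal length the difference from other genes was -2.47 percentage points, and adjusted p ranged from 0.00137 to 1 over the alternatives by these exact and permutation tests. B-cell identity genes lost H3K4me3 at 4 of 26 (CD22, CD37, CD72 and CR2; adjusted p = 0.566 by Fisher's exact test) and germinal centre exit genes at 3 of 18 (CD40, FCRL5 and NFKBIZ; adjusted p = 0.627). Without inhibitor replicate 1 the difference from other genes shrank from 9.74 to 6.24 percentage points for B-cell identity genes (Fisher's exact test, adjusted p = 1) and grew to 24.2 for germinal centre exit genes (adjusted p = 0.0548 by Fisher's exact test). The p53 targets lost it at 2 of 26 (CDKN1A and DDB2), immediate early genes at 3 of 27 (DUSP2, NR4A1 and PER1), NF-kB targets at 1 of 13 (TRAF1), cell cycle genes at 1 of 42 (AURKB) and myeloid markers at 1 of 3 (CD68). None was lost among 73 ribosomal protein, 45 acetyltransferase and coactivator, 27 MYC and ribosome biogenesis, 14 germinal centre, 6 MHC class II and 5 MHC class I genes.

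H3K4me1 was lost at LRRK2, a kinase gene (9437 and 6160 bp with DMSO), at RBL1, a relative of the retinoblastoma protein (5922 and 5575 bp), at NEK2, a mitotic kinase (5893 and 5998 bp), and near BPTF, a chromatin remodelling subunit (5403 and 5283 bp). The lost regions of highest rank lay at C2CD2, SUSD3 and RPTOR. The genes that gained it were CD34, IL22, RAB3IP, SHH and PXDNL, and the gained regions of highest rank lay in ACBD6 and BRINP3 and near CD34. RBL1 was no longer lost, and CD34, IL22, SHH and PXDNL no longer gained, with windows halved, and the states of RBL1, NEK2, CD34 and RAB3IP ended with windows 2.5 times as wide. Of 25624 H3K4me1 regions, 4417 were lost, 25 gained and 1826 present in all 4 libraries, against 446 and 441 changed regions in the other 2 splits and 4442 in the real split. At genes, 1851 of 4254 lost the mark (43.5%), against 6846 of 9626 (71.1%) without DMSO replicate 2. The 5 genes that gained it became 64 without DMSO replicate 1, 31 without inhibitor replicate 1 and 25 without inhibitor replicate 2. DMSO replicate 1 alone held 15752 regions (61.5%). Without DMSO replicate 2 the lost regions numbered 20257, and gained regions numbered 208 without DMSO replicate 1, 268 without inhibitor replicate 1 and 164 without inhibitor replicate 2. In lists of equal length, an alternative chosen after seeing the data, 587 were lost and 292 gained. The gene-end share was 30.8% ± 4.7 with DMSO and 23.7% ± 0.1 (SD, n = 2) with the inhibitor (exact permutation p = 0.333). That difference of -7.12 percentage points was -3.78 without DMSO replicate 1.

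No list passed the Fisher's exact test for H3K4me1 loss. B-cell identity genes lost it at 6 of 25 (PAX5, EBF1, BLNK and BCL11A among them), 24% against 43.6% of other genes. The one-sided tests could not call such lower loss. Germinal centre exit genes lost the mark at 6 of 13 (XBP1, CD38 and CD83 among them) and germinal centre genes at 5 of 11 (CXCR4 and FOXO1 among them). Interferon response genes lost it at 6 of 10 (MX1 and IFI35 among them). Immediate early genes lost it at 6 of 16, acetyltransferase and coactivator genes at 6 of 17, ribosomal protein genes at 10 of 20, p53 targets at 5 of 11, cell cycle genes at 4 of 14, NF-kB targets at 3 of 10, MYC and ribosome biogenesis genes at 3 of 5 and MHC class II genes at 3 of 4 (CD74, IFI30 and RFX5). Markers of T and NK cells lost it at 4 of 8 and epithelial and stromal markers at 1 of 4, while none of the 22 T and NK markers had H3K4me3 in any library. MHC class I presentation and myeloid markers had fewer than 3 background genes for H3K4me1, as did the epithelial and stromal markers for H3K4me3. Loss of H3K4me1 was counted even where the widest DMSO peaks did not overlap each other, as at PAX5, IFI35, IFI30 and RFX5. The DMSO replicate 2 peak at IFI35 was also that of RPL27, a ribosomal protein gene counted as lost.

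The genes named in the study's title and the lymphoma genes chosen with them had the following states. CREBBP lost H3K27ac (1660 and 783 bp with DMSO), and EP300 carried it in all 4 libraries (2569 and 1627 bp with DMSO, 1282 and 1785 bp with the inhibitor). CARM1 had an H3K27ac peak in inhibitor replicate 2 only and lost H3K4me1. BCL6, the germinal centre repressor, lost H3K27ac (1315 and 972 bp), whereas MYC and CD74, the MHC class II invariant chain, kept it in all 4 libraries, and CD74 lost H3K4me1. IRF4 had H3K27ac in 3 of the 4 libraries, CIITA in DMSO replicate 1 and inhibitor replicate 2, and PRDM1 in none. CARM1, CREBBP, EP300, CD74, CIITA, BCL6, MYC, PRDM1 and IRF4 had H3K4me3 in all 4 libraries. HLA-DRA lies in the stretch of chromosome 6 without peaks, so its lack of peaks is not read as a state of the gene. In lists of equal length, an alternative chosen after seeing the data, CREBBP and BCL6 no longer counted as lost for H3K27ac, nor CARM1 and CD74 for H3K4me1. The cut to the widest peaks removed their DMSO replicate 1 peaks (width percentiles 44.8, 25.3, 78.2 and 77.3). That setting therefore says nothing about a peak with the inhibitor at these genes. In the full DMSO replicate 2 lists their peaks were narrow (width percentiles 1.54, 10.3, 13.5 and 7.46, in the same order). Drop-out of peaks near the threshold is therefore not excluded for these losses.

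Replicates were compared by the base pairs their peaks shared. For H3K4me3, a promoter mark, the Jaccard index averaged 0.827 within treatments and 0.702 between them, and for H3K4me1 it averaged 0.362 and 0.206. For H3K27ac the means were 0.448 and 0.368, from 0.344 to 0.389 for the pairs between treatments. The H3K27ac inhibitor libraries shared 0.514 with each other and the DMSO libraries 0.382. Unequal covered length limits the index, as for the H3K27ac DMSO libraries (17.3 and 7.79 Mb) and for H3K4me1 between DMSO replicate 1 (60.4 Mb) and the inhibitor libraries (9.11 and 8.30 Mb), which shared 0.142 and 0.126.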

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

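The alternatives with the widest peaks in lists of equal length, random lists matched on peak width, the whole gene, peaks of 1 gene only, genes outside stretches without peaks, genes with H3K4me3 in all 4 libraries (for cell cycle genes) and 1 set of sites were chosen after seeing the data, as was every setting for the numbers of genes lost and gained; the others were planned. Score thresholds were not run, because the lists hold no score, and restricting chromosomes removed no peak. Leaving out a library loosens the rule for that group, so counts of lost and gained regions rise by construction. Of the values for the main comparisons, 135 kept their direction or size, 57 moved and 3 turned.

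In lists of equal length, lost regions numbered 463 for H3K27ac, 587 for H3K4me1 and 390 for H3K4me3, gained regions 292 for H3K4me1 and 188 for H3K4me3, and 1 list passed for loss; equal lengths themselves draw lost and gained counts together. With absence from at least 1 library of the other group, lost regions numbered 1441 for H3K27ac and 1885 for H3K4me3 and gained regions 1068, 198 and 22 for H3K27ac, H3K4me1 and H3K4me3, by construction. With 50% overlap, 38 H3K4me1 regions were gained. Leaving out each library in turn, lost regions ranged from 1034 to 3861 for H3K27ac, 5343 to 20257 for H3K4me1 and 1295 to 2276 for H3K4me3. Gained regions ranged from 405 to 1334, 29 to 268 and 12 to 386. The H3K27ac log2 ratio of peak number ranged from -0.75 to 0.22, turning only without DMSO replicate 1.

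Genes lost numbered 339, 264 and 242 for H3K27ac, H3K4me1 and H3K4me3 in lists of equal length, and 393 and 881 for H3K27ac and H3K4me1 with peaks of 1 gene only. Genes gained numbered 105, 121 and 118 in lists of equal length, 116 for H3K27ac and 8 for H3K4me3 with the whole gene, 12 for H3K4me1 and 28 for H3K4me3 with peaks of 1 gene only, and 1 for H3K4me1 with windows halved. Leaving out each library in turn, genes lost ranged from 758 to 2483, 1902 to 6846 and 624 to 989, and genes gained from 64 to 299, 5 to 64 and 1 to 5. Of the lost or gained states of named genes, 38 ended with windows halved, 40 with windows 2.5 times as wide and 27 with the whole gene. With peaks of 1 gene only 65 ended and in lists of equal length 91, and none turned under these settings. In the last 2 settings a state can end because the filter removed a peak from the libraries that had it.

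For the gene lists, 1 passed for loss with random lists matched on peak width and 0 with the whole gene, and 1 passed for gain with peaks of 1 gene only, which is not read as a gain, because 27 of the 28 genes gained for H3K4me3 under that filter, and 8 of the 12 for H3K4me1, had a peak in all 4 libraries without it, their DMSO peaks being dropped for touching another gene; from 2 to 3 passed for loss when a library was left out. In lists of equal length the difference from other genes turned to -2.47 percentage points for interferon response (H3K4me3) and to -11.1 for ribosomal proteins (H3K27ac), and the H3K4me3 gene-end share turned to -1.09. Within-treatment minus between-treatment overlap for H3K4me3 was 0.0548 by share of peaks. Against 1 set of sites the H3K27ac share at H3K4me1 only turned to 10.7 percentage points. The causes were not tested. Depth, which the lists do not give, limits all counts of absent peaks.

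The replicates share only a number, and no label ties same-numbered libraries to a day or culture. For the second inhibitor replicate the sample descriptions carry another number than the titles, from which the numbers here were taken. With the replicate number as a block, the log2 ratios of peak number were -0.27 for H3K27ac, -1.90 for H3K4me1 and -0.23 for H3K4me3, with an exact sign-flip p of 1, 0.5 and 0.5, where 0.5 is the smallest possible, so no call could change.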

Other observations

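The tests below of yield, lane, list length, background peaks, peak width at cell cycle genes and H3K4me3 width over the whole cell cycle list were chosen after their results or closely related values had been seen. The test of gene ends within width deciles and both tests of H3K4me3 width at cell cycle genes were written down before their results were seen.

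H3K4me3 narrowed more at cell cycle genes than at random genes of similar DMSO width. No other gene list was tested for this, and widths were summed over the peaks at both ends of a gene. All 14 cell cycle genes that lost H3K27ac kept H3K4me3 in all 4 libraries, and at all 14 both inhibitor libraries had narrower H3K4me3 than both DMSO libraries, as did 81.9% of all H3K4me3 regions in all 4 libraries, so the difference lies in the size of the narrowing. The covered length at E2F2 went from 4756 and 4046 bp with DMSO to 1244 and 961 bp, at MCM3 from 3019 and 2975 to 1654 and 1593 bp, at MCM5 from 2714 and 2444 to 1515 and 1315 bp, and at RRM2 from 5199 and 4962 to 3249 and 2813 bp. The log2 ratio nearest 0 was that of CDK4 (-0.18), from 7148 and 7270 to 6733 and 6031 bp. BIRC5, FOXM1, MYBL2 and TYMS are among the 14. Over the 41 cell cycle genes with H3K4me3 in all 4 libraries, the median log2 ratio was -0.56, while 10000 random lists matched on DMSO width had a median of -0.27 and a 95% range from -0.33 to -0.22.

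Genes that lost H3K27ac and genes that lost H3K4me1 overlapped. Among 1060 genes with both marks in both DMSO libraries, 114 lost both, against 87.8 expected (Fisher's exact test, odds ratio 1.80, adjusted p = 0.000298). Neighbouring genes that share a peak were counted separately, so this p-value can be too small. The test was not matched on peak width, so narrow peaks dropping out for both marks at the same genes are not excluded. The overlap of H3K4me3 loss with H3K27ac loss (8 genes against 6.21 expected) and with H3K4me1 loss (112 against 119.007) did not pass the test (Fisher's exact test, adjusted p = 0.475 for each).

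The first pattern is that cell cycle genes lost H3K27ac more often than other genes. The explanation that narrow peaks drop out first is argued against only as far as the mean width percentile over the 2 DMSO libraries goes. None of 10000 random lists matched on that mean reached 14 losses (permutation p = 0.0001, the smallest they can give). The lists were not matched on DMSO replicate 2 alone. There the 14 include narrow peaks, as at E2F8 (687 bp, percentile 0.31) and MCM5 (801 bp, percentile 2.13), but also E2F2 (2565 bp, percentile 81.9). Drop-out of peaks near the threshold in that library is therefore not excluded. A hypothesis is lower activity of these promoters in the inhibitor libraries, which predicts narrower H3K4me3 as well. The median log2 ratio at the 14 genes was -0.57, at percentile 0 of the random lists. Over all 41 cell cycle genes with H3K4me3 in all 4 libraries it was -0.56. The narrowing was thus not particular to the list members that lost H3K27ac. H3K4me3 also narrowed at the other genes that lost H3K27ac (median log2 ratio -0.30). That it narrows as much at any gene that lost H3K27ac is argued against. The median of the 14 genes stood at percentile 0.02 of lists drawn from the other 612 genes that lost H3K27ac, whose lists had a median of -0.31. Slower division after CARM1 inhibition, the treatment in the design, may account for this and was not tested; lane remains open for it as well.

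The second pattern is that H3K27ac peaks lay less often at gene ends with the inhibitor. List length as the only cause is argued against, since the difference of means was -12.6 percentage points in lists of equal length. The largest difference between 2 libraries of a treatment was 7.10. The cut by width left the list of DMSO replicate 2 whole and lowered the share in DMSO replicate 1 from 51.5% to 44.2%. Inhibitor replicate 1 had 36.8%, so length does shift the share and the margin between single libraries is narrow. Gained regions by definition had a peak in both inhibitor libraries, so background placed independently in each library was mostly left out beforehand. The regions in inhibitor replicate 1 only (702) or inhibitor replicate 2 only (920) were not tested. For the gained regions, background that recurs in both libraries without regard to H3K4me1 is argued against. Of these regions 73.6% overlapped DMSO H3K4me1 peaks, against at most 13.8% for the same regions moved by 20 to 100 kb. Background that gathers at H3K4me1 sites would overlap them as well, and inputs were not used, so the test cannot decide on it. For the lost regions a candidate explanation is that narrow peaks at gene ends drop out first, because within width deciles gene-end regions were lost no more often than others (-1.95 percentage points). That does not account for the gained regions, and a shift of acetylation towards distal sites under CARM1 inhibition stays open and untested.

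The third pattern is that far more H3K4me1 and H3K4me3 regions were lost than gained. A lower yield of peaks in the inhibitor libraries goes with the widths in the DMSO replicate 2 list. Each region was ranked by its widest peak there, which favours regions with several peaks. Lost regions had a median width percentile of 37.3 for H3K4me1 and 9.16 for H3K4me3. Regions kept in all 4 libraries had 85.5 and 57.7. A weaker mark at all sites would look alike, so treatment stays open. Sequencing lane cannot be told apart from treatment, because 0 lanes hold libraries of both treatments.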
